A study of Drosophila melanogaster with 4 samples.

How the data were processed

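Chromatin immunoprecipitation followed by sequencing was carried out on Drosophila melanogaster embryos 8 to 16 h old that carried a transgene of the Eip74EF genomic region tagged with GFP. Eip74EF is an ecdysone-induced gene whose product has an ETS-type DNA-binding domain. Per the labels, embryos were cross-linked in 1.8% formaldehyde for 15 min, and a rabbit polyclonal antibody against GFP was used for the precipitation. The 4 libraries were 2 precipitated samples and 2 samples of input DNA, which is chromatin DNA that was not precipitated and serves as the background. The titles gave the group and the replicate number of each library.

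The authors deposited 1 list of called peaks for the whole series, with a position and 1 peak score for each peak and no value for any single library. Per the file headers, positions refer to FlyBase release 5 of the fly genome, and the source column names MACS as the peak caller. Per the submitters' processing notes, CASAVA (1.7.0.2 and 1.7.0.3), BWA and MACS2 were used with the build BDGP5. The caller's settings, the threshold, the scale of the score and any filter between replicates are not given in the sources used here. Whether the 2 precipitated libraries were pooled before calling, or peaks were called per library and then combined, is not given either. The score is therefore used only to rank and to describe peaks within this list. No read counts came with the list, so the depth per library is unknown and no value carries an error between replicates. All p-values and intervals below treat peaks, or stretches of a chromosome arm, as the units. They cover the placement and ranking of peaks in this list and say nothing of the spread between embryo collections.

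Before the data were examined, 7 kinds of result were planned. Only 2 of them could be computed, and for the peaks by arm the test departed from the plan, as given below. The gene table at hand follows release 6 of the genome while the peaks follow release 5, and coordinates were not carried from one to the other, so no peak was assigned to a gene. The share of peaks at transcription start sites, the score of such peaks, the ETS motif and 11 other motifs in peaks, and the membership of bound genes in 21 gene lists were therefore not analysed here. The planned rule for named items began with Eip74EF and the genes nearest to the 15 peaks of highest score, and went on to bound members of each list. It was applied to positions only, for those 15 peaks, the 3 widest peaks and the 3 places with most peaks within 50 kb.

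Peaks were counted on each of the 13 sequences that held any. The arm length was taken as the span from the first to the last peak, since no release 5 sequence was used here. Counts on the 6 arms (2L, 2R, 3L, 3R, 4 and X) were tested against the shares of span with an exact binomial test, two-sided, with Benjamini-Hochberg adjustment over 6 arms. The plan called for counts alone where no sequence of the build was given, so testing against span departed from it. This test takes peaks as independent, which neighbouring peaks are not. Density ratios therefore also carry a 95% percentile interval from 10000 bootstrap draws of 100 kb bins. X and the 4 large autosomal arms were further compared by permuting bins of 1 Mb 100000 times, in all peaks and in each of 4 equal classes by score (under 12.3, 12.3 to 17.87, 17.87 to 33.04 and above), 5 tests with Benjamini-Hochberg adjustment. This permutation left out the dense run on 2L and the incomplete last bin of each arm, and so used 211 of the 214 peaks on X and 1210 of the 1237 other peaks on the large autosomal arms. Median scores and widths were compared by permutation tests with 100000 resamples, 8 tests adjusted together. Shares of high-scoring peaks were compared by Fisher's exact test, two-sided, and carry exact Clopper-Pearson 95% intervals, which cover counting error only. The tests of medians and Fisher's exact test also take peaks as independent.

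Peak spacing was measured as the share of peaks whose midpoint lay within 10 kb of the midpoint of another peak. It was compared, one-sided, with 1000 random placements of peaks of the same widths between the first and the last peak of each arm, in which peaks were allowed to overlap. Runs of peaks were formed by joining peaks separated by gaps of at most 10 kb. In 1 dense run, the step at which peaks recurred was sought between 2 and 10 kb as the step with the greatest resultant length. That quantity is 1 when all positions fall at the same phase of the step and near 0 when the phases are spread. It was compared with 10000 sets of random positions drawn between the first and the last midpoint of the set. These were free to overlap, unlike called peaks. The ranks of the scores of the run's peaks were searched for a step in the same range and compared with 10000 permutations of the scores over the same positions. The run, both searches for a step, the density ratios and the comparisons of scores, widths and score classes were chosen after the data were seen.

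The alternatives were a stricter list (the 967 peaks with a score of at least the median, 17.87), neighbours within 5 or 20 kb, lists without the dense run, merging of nearby peaks, arm lengths counted from position 1, bins of 1 Mb, and random shifts of each peak by up to 100 kb. The spacing test, the median test and both searches for a step were tried on simulated data; the exact binomial test, the permutation of bins and Fisher's exact test were not. The spacing test gave p under 0.05 in 3 of 100 random lists and in 100 of 100 lists with added neighbours. The median test did so in 5 of 100 lists with no shift and in 99 of 100 with scores raised 1.3 times. The period search did so in 3 of 100 random sets and found a 5000 bp step in 100 of 100 sets made with one. The search of the scores gave p under 0.05 in 4 of 100 sets with no step and in 100 of 100 with scores raised every 5000 bp. The lists for the median test were permuted scores, so they held no clustering of scores along an arm. Whether the bootstrap intervals cover a known ratio was not tried. Those of chromosome 4, with a span of 1.28 Mb, draw on few bins and may be too narrow. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.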

Results

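To locate the chromatin bound by the tagged Eip74EF protein in embryos 8 to 16 h old, 2 anti-GFP precipitations and 2 input samples were sequenced, and 1 list of 1929 peaks was deposited for the series. Which libraries entered the list is not given. No anti-GFP precipitation from embryos without the tag was among the libraries. Precipitation unrelated to the tagged protein therefore cannot be told apart from its binding. The peaks covered 952 kb in all. They were mostly narrow: the median width was 404 bp (quartiles 289 and 602 bp), 93.5% of peaks were under 1 kb wide, and the widest measured 3282 bp. The authors' peak scores ran from 6.02 to 333.18 with a median of 17.87 (quartiles 12.3 and 33.04), on a scale the sources used here do not give. Wider peaks had higher scores (Spearman's rho of 0.72 across peaks, which are not independent replicates). The list names no genes, and no gene was assigned to a peak. Depth per library is unknown, and no value has an error between replicates.

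The 15 peaks with the highest scores all lay on the large autosomal arms (2L, 2R, 3L and 3R). Arm 3R held 7 of them, 2R and 3L held 3 each, and 2L held 2. The highest score in the list, 333.18, belonged to a peak on 2R at 15993651 to 15994429 (release 5). On 3R, the peak at 17405176 to 17406743 scored 293.85 and opened a run of 7 peaks that reached 17417930. A second strong site on 3R held 3 adjacent peaks between 2644508 and 2648563, of which the peaks starting at 2645943 and 2647608 scored 293.68 and 246.13. An isolated 3R peak at 18222837 to 18223509 scored 275.91. On 2L, the run of 4 peaks between 4996716 and 5004811 included the widest peak of the list (4999781 to 5003062, score 256.57) and a 1937 bp peak with a score of 248.06. The strongest 3L peak lay at 18081058 to 18081638 and scored 216.36. The highest score on X was 160.49 and on chromosome 4 it was 115.82. The second and the third widest peaks were 2497 bp on 2R (431929 to 434425, score 63.49) and 2313 bp on X (11029727 to 11032039, score 93.28).

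Chromosome 4, the small autosome that is largely heterochromatic, was far more densely covered with peaks than any other arm. It held 73 peaks in a span of 1.28 Mb, which is 56.8 peaks per Mb, against 13.7 per Mb on 2L, 2R, 3L and 3R together. The ratio was 4.14 (95% bootstrap interval 3.22 to 5.29), and the exact binomial test against span gave an adjusted p of 5.69e-23. Apart from the dense run on 2L described further on, no window of the same length on the other 5 arms held more than 36 peaks. The excess was present among strong peaks: in the highest of 4 equal score classes the ratio was 6.96 (4.48 to 10.0), and 29 of the 73 peaks (39.7%, interval 28.5 to 51.9%) fell in that class, against 23.6% on the large autosomal arms (Fisher's exact test, adjusted p = 0.0061). In the third class, with 8 peaks, the interval included 1 (ratio 1.94, 0.464 to 3.75). The median score of chromosome 4, 18.82, was not distinguishable from the 16.94 of the large autosomal arms (permutation test, adjusted p = 0.45; interval of the difference -2.9 to 16.1). Its median width was 492 bp against 392 bp (permutation test, adjusted p = 0.02), although the bootstrap interval of the difference, -18 to 200 bp, included 0.

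**Figure D1:**
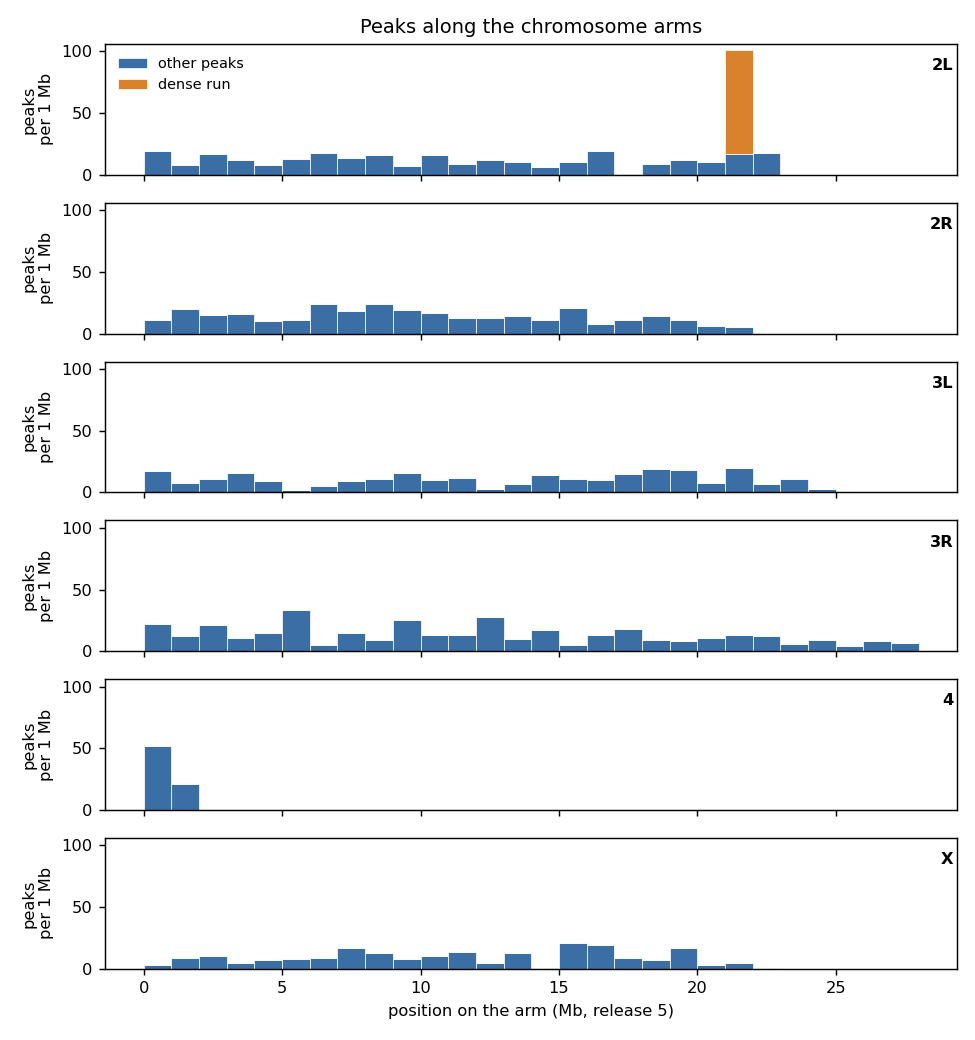
Number of peaks (vertical axis) in consecutive 1 Mb bins along each arm (horizontal axis, Mb, release 5), with the dense run on 2L in orange and all other peaks in blue; the last bin of each arm is incomplete. The first bin of chromosome 4 holds 52 peaks, and the bin of 2L from 21 to 22 Mb holds 101, of which 84 belong to the dense run.

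Peaks were sparser on the X chromosome than on the large autosomal arms, though not in the highest score class, and their median score was higher. X held 214 peaks, or 9.92 per Mb, which was 0.72 times the density of the large autosomal arms (95% bootstrap interval 0.573 to 0.894). The exact binomial test over the 6 arms gave an adjusted p of 7.51e-07, which may be too small since it takes peaks as independent. From the lowest to the highest score class the ratio was 0.53 (0.360 to 0.724), 0.69 (0.488 to 0.946), 0.61 (0.428 to 0.826) and 1.10 (0.785 to 1.49), so it did not rise steadily with the score. With the dense run on 2L and incomplete bins left out and bins of 1 Mb permuted, the lowest class averaged 2.00 ± 1.61 peaks per bin on X (SD over 21 bins) and 3.76 ± 2.48 on the large autosomal arms (SD over 94 bins), a difference with an adjusted permutation p of 0.013. The same permutation test did not separate X from the autosomes in the second class (adjusted p = 0.185), the third class (adjusted p = 0.079), the highest class (3.67 ± 4.29 against 3.09 ± 1.93, adjusted p = 0.36) or over all peaks (10.0 ± 6.54 against 12.9 ± 5.61, adjusted p = 0.079). The interval of the density ratio over all X peaks also reached 1 when peaks within 10 kb were merged (0.845, 0.695 to 1.006) and in the stricter list of peaks at or above the median score (0.856, 0.651 to 1.09).

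The median score on X was 21.66 against 16.94 on the large autosomal arms, a difference of 4.72 (bootstrap interval 0.180 to 9.96; permutation test, adjusted p = 0.00069). In the stricter list the difference was 5.64 and did not pass the test (permutation test, adjusted p = 0.0998). Peaks on X were also wider, with a median of 483 bp against 392 bp (difference 91 bp, interval 45 to 133 bp, permutation test, adjusted p = 0.00069). Of the X peaks, 77 (36.0%, interval 29.6 to 42.8%) were in the highest score class, a larger share than the 23.6% on the large autosomal arms (Fisher's exact test, adjusted p = 0.00074). The share and the median describe the same scores and are not separate evidence. Both tests take peaks as independent, but peaks of the highest class were spread unevenly over X. Their SD over 1 Mb bins was 4.29, against 1.93 on the large autosomal arms without the dense run. The p-values may therefore be too small.

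**Figure D2:**
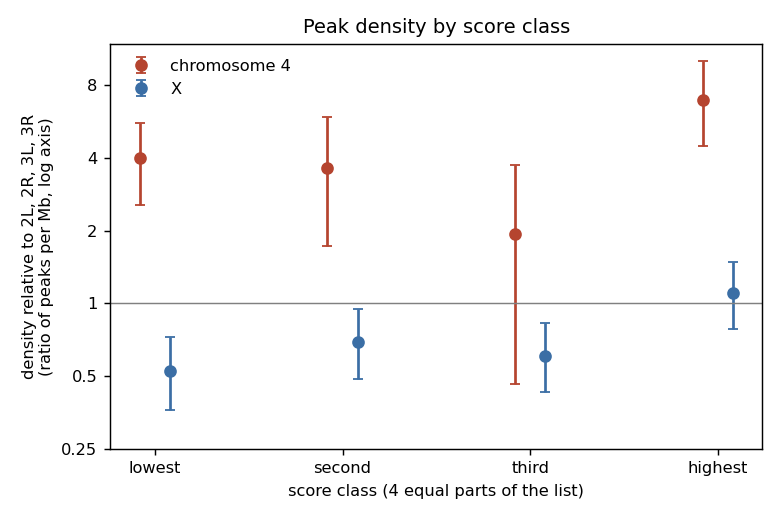
Peak density on chromosome 4 (red) and X (blue) relative to 2L, 2R, 3L and 3R together (vertical axis, ratio of peaks per Mb, log axis) in each of 4 equal classes of the list by peak score (horizontal axis); points are ratios and bars are 95% bootstrap intervals over 100 kb bins. X lies under 1 in the lower 3 classes and at 1.10 in the highest, where chromosome 4 reaches 6.96.

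Among the large autosomal arms, 3L was the most sparsely covered. It held 272 peaks, 11.1 per Mb and 0.82 times the number its share of span would give (exact binomial test, adjusted p = 0.00053). Without the dense run on 2L the ratio of 3L was 0.87 (exact binomial test, adjusted p = 0.014). The longest stretch of an arm without a peak was also on 3L, 920 kb between 4825887 and 5746067. Arm 2L, with 365 peaks, stood above its share of span (ratio 1.18, exact binomial test, adjusted p = 0.00084), but this rested on the dense run: without it 281 peaks remained and the ratio was 0.96 (adjusted p = 0.45). Arm 2R held 312 peaks (ratio 1.10, exact binomial test, adjusted p = 0.080), and without the dense run on 2L its ratio of 1.16 passed the test (adjusted p = 0.0095). Arm 3R held 372 peaks (ratio 0.99, exact binomial test, adjusted p = 0.84). The binomial test takes neighbouring peaks as independent, and no interval over bins was computed for these arms singly. The p-values of this test for 3L, 2L and 2R, like those for chromosome 4 and X, may therefore be too small.

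Peaks lay closer together than random placement would put them on 2L, 2R, 3L, 3R and X, and no such excess was found on chromosome 4. Of the 1608 peaks on the 6 arms, 53.4% had another peak within 10 kb, compared with 25.4% ± 1.38 (SD over 1000 placements) when peaks were placed at random; p was 0.001, the smallest that 1000 placements can give. Leaving out the dense run gave 50.9% against 24.3%. With peaks within 1 kb also merged, the share fell to 34.6% against 20.9%, or against 25.5% when each peak was moved by up to 100 kb. On X the share was 43.9% against 17.8%, on 3L 50.7% against 19.6%, on 3R 49.7% against 23.4%, on 2R 48.4% against 25.5%, and on 2L without the dense run 56.2% against 21.7%, each with the same smallest p. On chromosome 4, where random placement alone already gave 67.7% ± 5.87, the observed share was 67.1% (permutation of positions, p = 0.59). Joining peaks over gaps of at most 10 kb gave 1027 runs on the arms, of which 735 were single peaks, 176 held 2 peaks and 116 held 3 or more. Apart from the dense run, the largest runs had 10 peaks on 3R (9837698 to 9862099, highest score 75.69) and 9 peaks on 3L (21000805 to 21020466, highest score 62.98). A run of 6 peaks on 2R (6305441 to 6325753) had the high median score of 75.81.

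Peaks with a near neighbour had a lower median score than isolated ones. The median score was 16.02 for the 859 peaks with another peak within 10 kb and 19.16 for the 749 without, a difference of -3.14 (bootstrap interval -4.71 to -1.88; permutation test, p = 1e-05, the smallest that 100000 resamples can give). Without the dense run the difference was -3.44. The test takes peaks as independent, which peaks lying near each other are not, so the p-value may be too small.

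**Figure D3:**
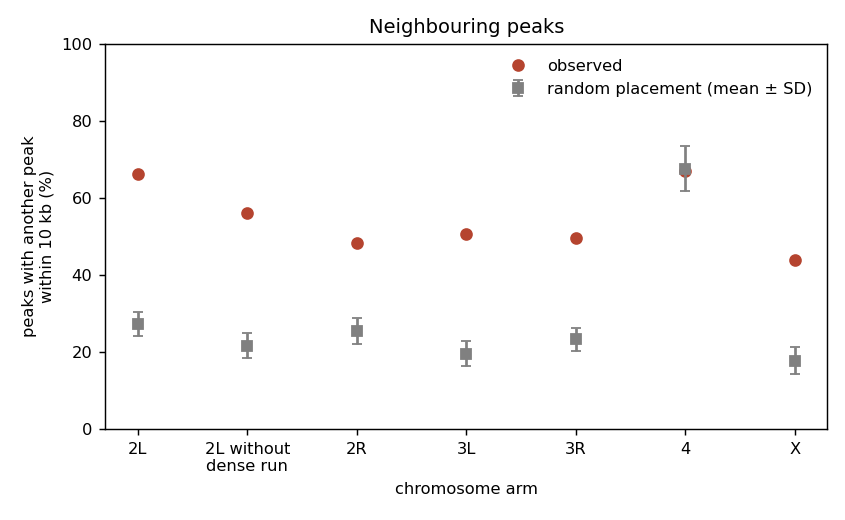
Percentage of peaks with another peak within 10 kb (vertical axis) on each chromosome arm (horizontal axis); red circles are observed values and grey squares with bars are the mean and SD of 1000 random placements. Observed shares stand between 43.9% and 66.3% on 2L, 2R, 3L, 3R and X, above random placement, and at 67.1% on chromosome 4, where the 2 symbols coincide.

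The 3 places with most peaks within 50 kb were all in 1 stretch near the centromeric end of 2L, with 40, 29 and 16 peaks. Apart from the first peak of the place with 16, their peaks belonged to a run that extended from 21416574 to 21543306 and held 84 peaks in 127 kb, or 663 per Mb. It took up 0.55% of the span of 2L and accounted for 84 of the 365 peaks on that arm. Its scores were moderate, from 7.14 to 44.62 with a median of 17.09, and 15 of its peaks were in the highest score class of the list. The strong peaks of the run recurred at a regular distance. For the 21 peaks of the run with the highest scores, those above 26.6, the best step was 5014 bp with a resultant length of 0.881, above the highest of 10000 random sets, 0.742 (permutation of positions, p = 0.0001, the smallest possible). Of the 20 distances between neighbours among these peaks, 16 were within 10% of that step. For the 42 peaks at or above the median score of the run the best step was 2497 bp (resultant length 0.545, permutation of positions, p = 0.0002), and for the 42 peaks under it 4985 bp (resultant length 0.522, permutation of positions, p = 0.0009). The positions of all 84 peaks did not pass the test (best step 2498 bp, resultant length 0.275, permutation of positions, p = 0.21). With positions kept and the scores permuted over the 84 peaks, the rise and fall of the scores along the run was strongest at a step of 5019 bp (permutation test, p = 0.0001, the smallest possible). Outside this run, the densest place held 12 peaks, on 3R from 9837698 to 9882825.

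**Figure D4:**
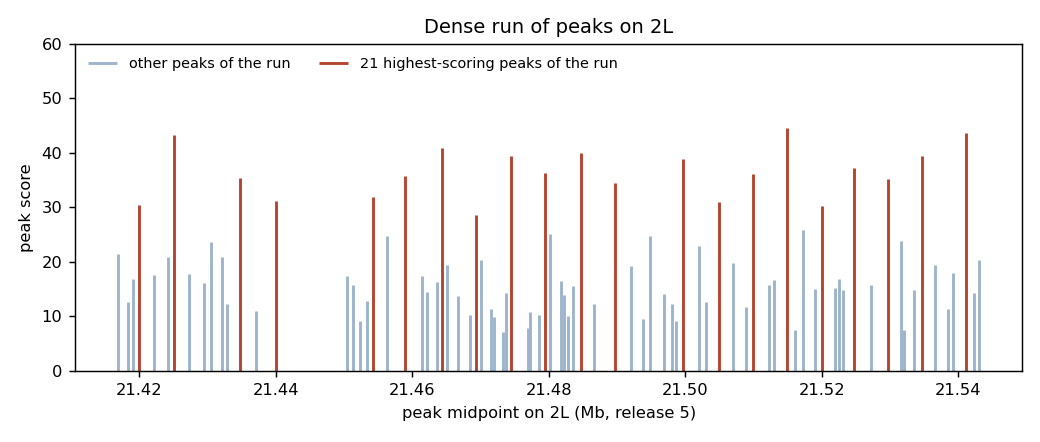
Score (vertical axis) of each of the 84 peaks of the dense run against its midpoint on 2L (horizontal axis, Mb, release 5); red lines mark the 21 peaks of the run with the highest scores and pale blue lines the rest. The red lines recur about every 5014 bp, and the highest reaches a score of 44.62.

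Sequence outside the 6 arms held 321 peaks, 16.6% of the list. Uextra, a concatenation of scaffolds not placed on any chromosome, accounted for 259 of these (13.4% of the list, interval 11.9 to 15.0%). Its scores had quartiles of 15.2 and 30.2. The median was 20.48, which was 3.54 above that of the large autosomal arms (interval 2.14 to 4.97; permutation test, adjusted p = 0.00069), yet none passed 78.11, a score that 140 peaks on the arms (8.7%) exceeded. The highest score class held 50 of the Uextra peaks (19.3%), against 23.6% on the large autosomal arms (Fisher's exact test, adjusted p = 0.16). No Uextra peak was wider than 804 bp, a width that 219 peaks on the arms (13.6%) exceeded. The heterochromatic scaffolds of 2L, 2R, 3L, 3R and X together held 46 peaks, of which 22 were on 2RHet and 13 on 3LHet. Their median score of 17.7 was not distinguishable from that of the large autosomal arms (interval of the difference -3.85 to 11.8; permutation test, adjusted p = 0.78). The unplaced sequence U held 16 peaks, with a highest score of 36.77.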

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

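The higher density on chromosome 4 kept its direction under all 5 alternatives tried, with ratios between 3.80 and 4.47. The peak spacing stood above its random placements under all 10 of its alternatives, among them merging peaks within 1 kb without the dense run (34.6% against 20.9%). It also did so when each such peak was moved by up to 100 kb rather than placed anywhere (34.6% against 25.5%). The lower density on X did not keep its call in every alternative. The ratio was 0.856 in the stricter list, 0.845 after merging peaks within 10 kb and 0.846 after merging without the dense run. In each of these the interval included 1. The interval stayed under 1 without the dense run alone (0.771, 0.622 to 0.944), with arm lengths from position 1 (0.707, 0.559 to 0.879) and with bins of 1 Mb (0.722, 0.526 to 0.972). The higher median score on X kept its direction in 3 alternatives. It lost its call in the stricter list (difference 5.64, permutation test, adjusted p = 0.0998), kept it within classes of width (4.40, adjusted p = 0.037) and kept it without the dense run. The adjustment takes the other 7 comparisons as in the main test. Without the dense run, 2L fell from 22.7% to 18.4% of the arm peaks, its ratio to span turned to 0.959 and that of 3R to 1.04, because the run's 84 peaks left the total. In the stricter list, X made up 15.3% instead of 13.3% of the arm peaks, and the ratios to span of 2L (1.13, exact binomial test, adjusted p = 0.11) and X (0.85, adjusted p = 0.090) no longer passed the test. The cause was not tested. Alternatives set out before the data were examined that need transcription start sites, sequence or genes were not run. No paired analysis was possible because the list holds no value for a single library, and for the same reason no replicate could be left out and the depth behind a peak cannot be stated.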

Other observations

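The tests of the dense run, of the strong peaks on chromosome 4 and of the score classes on X were chosen after the results were seen, and the 2 tests that merged peaks within 10 kb were set out before their values were known. The design holds 1 strain, 1 stage and 1 antibody, so no biological explanation was tested for any of the 3 patterns.

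One hypothesis for the dense run on 2L is tandemly repeated DNA whose copies share reads. Among the 42 peaks at or above the median score of the run, which was the set named for the test, the best resultant length was 0.545 at a step of 2497 bp, and the 21 highest-scoring peaks recurred every 5014 bp. The 42 peaks under that median also recurred, at 4985 bp (resultant length 0.522, permutation of positions, p = 0.0009), although the sets come from 1 split by score and are not independent. Permuting the scores over all 84 peaks, with positions kept, matched the step in the scores in none of 10000 draws (permutation test, p = 0.0001). This argues only against a background whose scores fall at random over the peaks. A background that rises and falls with each copy of a repeat was not tested. The test uses the same scores and positions as the step of the 21 highest-scoring peaks, so it is not separate evidence. For the positions of all 84 peaks, calls broken off at chance places cannot be told apart from a repeat (resultant length 0.275, permutation of positions, p = 0.21), since several peaks in each copy would also spread the phases. The run is about 25.3 steps long, and the tandem array of histone genes, a repeat of about 5 kb near the base of 2L, is a candidate source. That identity was not checked, since no release 5 annotation was used here, and whether the tagged protein binds each copy or reads from a few copies were spread over all stays open.

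Weak calls and split calls were set against the density on chromosome 4. After merging peaks within 10 kb the lower bound of the density ratio was 3.10, above 1. This argues against calls split within that distance as the whole cause. In the highest score class the lower bound was 4.48. That criterion was named after the ratio was seen, so it describes an excess among strong peaks and is no separate test of weak calls. Both intervals rest on few 100 kb bins of chromosome 4 and may be too narrow. Repeated sequence on this chromosome and a closer packing of genes or regulatory sites may each contribute, and neither could be examined without the sequence and annotation of release 5.

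A loss of weak calls was weighed against the lower density on X. From the lowest to the highest score class the ratio to the large autosomal arms was 0.53, 0.69, 0.61 and 1.10. The interval lay under 1 in the lowest class (0.360 to 0.724) and reached 1 in the highest (0.785 to 1.49). These values were named for this explanation only after the ratios were seen, so meeting them does not support it. The third class, above the median score of the list, is less clear, since its interval (0.428 to 0.826) also lay under 1 while the permutation of complete 1 Mb bins without the dense run did not separate X from the autosomes (adjusted p = 0.079). The explanation stays open. Male embryos have 1 X chromosome, so lower coverage of X in a mixed collection is a candidate cause, but coverage was not measured here. Lower coverage could also lower the scores of strong X peaks. The highest class was not visibly thinned, however (ratio 1.10, 0.785 to 1.49). The median score was higher on X (21.66 against 16.94), though a loss of weak calls would raise it too. The scale of the score is unknown, so these values cannot settle the matter. After merging peaks within 10 kb without the dense run, the ratio was 0.846 (interval 0.695 to 1.005). Merging over a fixed distance joins more peaks where they are denser, whether or not they cluster. It therefore cannot decide whether more clustering of autosomal calls contributes. The loss of weak calls and the clustering of calls overlap as explanations, since peaks with a near neighbour had a lower median score than isolated ones.

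Uextra peaks had a near neighbour in 24.3% of cases against 17.3% under random placement (permutation of positions, p = 0.016), a comparison that takes the joined scaffolds as 1 sequence.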
